A study of Rhizobium favelukesii with 6 samples.

How the data were processed

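The series holds 6 RNA libraries of Rhizobium favelukesii strain LPU83, 3 from batch culture at pH 4.6 and 3 at pH 7.0, as the labels give them. Per the labels, cells were treated with RNA Protect, RNA was extracted with RNeasy columns and treated with DNase I, ribosomal RNA was depleted with Ribo-Zero, and stranded libraries were made with a TruSeq kit. The submitters' notes name Trimmomatic, Bowtie2, DESeq and DESeq2 without versions or the step each served.

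Per the labels and headers, the authors deposited raw counts per gene for 7693 genes in each library. The program that counted, its strand setting and the genome build are not given in the sources used here. Gene coordinates were taken from the same table. The authors also deposited a table in the form that DESeq2 writes, with a mean signal per gene (normalised counts averaged over the 6 libraries), log2 fold changes with standard errors, a Wald score, and p-values before and after adjustment; 25 p-values were missing in it. Its sign was settled from the counts: positive means higher at pH 4.6. The authors' start site table gives counts of read starts, the coverage signal gained at each site and that gain as a percentage score, and their operon table gives reads that span neighbouring genes. Per the deposited parameter sheets both were made with ReadXplorer 2.2.3 on all 6 libraries together. Start sites needed 50 read starts and a coverage increase of 50%, with lower limits of 10 to 20 read starts at low coverage, and neighbours in a window of 3 bp were joined. Operons needed 5 spanning reads, uniquely mapped; the start site search also took multiply mapped reads. The start site sheet counts 4206 sites and 94 leaderless ones where the table holds 4205 and 89; 1 line of the table was emptied for this work.

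Product texts were taken from the start site table, the source of gene names used here. It names a product for 832 genes, 826 of them on the reverse strand, and 555 of these are known products (other than hypothetical, unknown, uncharacterised, conserved or of a family of unknown function). That last exclusion was completed after the largest changes had been seen, and removes LPU83_3077, of an unknown family, with a log2 fold change of 3.17. Of neighbouring gene pairs 1360 overlap, 229 of them on opposite strands; of the 53 genes named by rule, 9 overlap another gene and 1 overlaps one on the opposite strand. Most listed lengths, 7645 of 7693, are multiples of 3.

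Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling factors, the filter filterByExpr, the quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjusted p under 0.05. A gene was called at least 2-fold changed if its absolute log2 fold change was also at least 1. Standard errors are the absolute log2 fold change over the square root of F. CPM values are counts divided by the library total scaled by TMM, on the usual scale of edgeR. All gene rows entered, RNA genes included, and 301 genes fell to the filter. Totals of 11931992 to 15169257 counts per library limit precision less than the spread between replicates does: the chi-square per degree of freedom between pairs of replicates, which is near 1 for counting error alone, was 15.1 for pH 4.6 replicates 1 and 3 and from 92.0 to 161.9 for the other pairs.

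Gene lists were matched by product text alone. They were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 18 lists with at least 3 tested genes; of the others, 7 held 1 or 2 members and 4 none. Calls of replicons used Fisher's exact test over 5 replicons and both directions. Operon pairs were compared by a permutation test with 100000 resamples. The rule for named genes took the 10 largest rises and 10 largest falls with a known product, and the largest rise and fall without one, among genes past the test with a mean log2 CPM of at least 5 and no overlap between the groups. From each list it took the 2 members past the test with the smallest adjusted p in each direction, whatever their CPM or overlap. Further list members are named to give the makeup of a list. The lists, this rule, the tests and most alternatives were fixed before the data were examined.

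These alternatives were DESeq2 1.42.0, RLE scaling factors, library totals, no filter on low counts, a filter of 1 CPM in at least 3 libraries, omission of rRNA and tRNA genes, the replicate number as a block, omission of each library in turn, glmTreat against a fold change of 2, camera with an estimated correlation, and fry. TMM factors from chromosomal genes alone, the block, the omission of libraries and the omission of overlapping pairs for the operon comparison, the TCA cycle list without 3-isopropylmalate dehydrogenase, and the medians of operons and lists without each library, were added after the data were seen. The procedures were tested on simulated data with the dispersions of these libraries and 3 libraries a side. With 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 36% and 98% of them, with 4.29% false calls. DESeq2 recovered 56% and 98% with 13.0% false. A far larger share of genes was called in the data, so these rates need not hold there. A raised list was found, and with no effect no list was called. Genes were drawn independently in these list runs, so they do not test the calls of lists whose genes correlate. A correlation of 0.6 set inside operons came back as 0.60.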

Results

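Transcripts of Rhizobium favelukesii LPU83, a nitrogen-fixing soil bacterium with a chromosome and 4 plasmids (pLPU83a to pLPU83d), were counted by RNA sequencing after batch culture in SG medium at pH 4.6 or at pH 7.0. There were 6 libraries, 3 at each pH, and the pH was the one factor that the labels set apart. The series names the response to acid stress as its subject. The totals were 15040078, 14327417 and 13697334 counts in the pH 4.6 libraries and 11931992, 14088157 and 15169257 in the pH 7.0 libraries. Of 7693 genes listed, 7392 had enough counts to be tested. The labels do not say whether the samples came from separate cultures, so the p-values measure the spread between these samples only.

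Replicates of pH 4.6 did not lie equally close together. Across genes, which are not independent replicates, log2 CPM (counts scaled to a common library total) of replicates 1 and 3 correlated with Pearson's r = 0.993, and those of replicate 2 with r = 0.971 and 0.970. At pH 7.0 the 3 values were 0.975, 0.980 and 0.981. Between the groups r lay between 0.874 and 0.899. Counts of the 23 genes listed as rRNA or tRNA made up 0.716% of pH 4.6 replicate 2, against 0.243% and 0.300% of the other pH 4.6 libraries and 0.226 to 0.236% at pH 7.0.

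The first question was which genes differ between acid and neutral culture. Among genes with a known product, a mean log2 CPM of at least 5 and no overlap between the groups, those of a beta-lactamase, a multidrug efflux transporter, a chloride channel and the flagellar motor protein MotA were among the 10 that rose most at pH 4.6. The 10 that fell most included genes for a conjugal transfer protein, a heme receptor and a heme-degrading enzyme. The gene for the conjugal transfer protein TraA on pLPU83b, LPU83_pLPU83b_0344, averaged 77.1 ± 58.3 CPM at pH 4.6 and 11447 ± 3774 CPM at pH 7.0 (SD, n = 3). The heme receptor gene LPU83_2981 averaged 135 ± 34.5 against 6037 ± 872 CPM.

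By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3173 of the 7392 genes changed (42.9%), 1529 of them higher and 1644 lower at pH 4.6. At least a 2-fold difference was estimated for 1965 of them, 826 higher and 1139 lower; tested directly against a 2-fold change with glmTreat, 789 passed, 294 higher and 495 lower. In 3098 of the changed genes the 3 libraries of one pH all lay above the 3 of the other; among all tested genes 3952 did (53.5%), where chance gives 10%. The balance of directions depends on how the libraries are scaled. Scaling factors taken from chromosomal genes alone, an alternative chosen after the data were seen, moved the median log2 fold change by -0.23 and gave 1048 genes higher and 2106 lower, with 535 at least 2-fold higher, whereas library totals moved it by 0.10 and gave 1681 and 1423.

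Among the genes that met these conditions, the largest rise was that of the beta-lactamase gene LPU83_pLPU83d_0054 on pLPU83d (55703 to 56887), an enzyme that opens beta-lactam rings. Its log2 fold change was 3.58 ± 0.23 (SE, edgeR adjusted p = 7.1e-06), from 14.3 ± 2.66 to 171 ± 19.98 CPM (SD, n = 3). The gene for a multidrug efflux transporter, LPU83_3678 (chromosome 3639702 to 3640901), rose by 3.38 ± 0.26 on the log2 scale. A chloride channel gene, LPU83_2116, rose by 3.03 ± 0.28; it overlaps LPU83_2115 on the opposite strand. A permease gene of the galactoside transport family (mglC homolog), LPU83_3205, rose by 2.95 ± 0.31, and the motA gene LPU83_0790, whose product is part of the stator that drives the flagellum, by 2.53 ± 0.22. Genes for the substrate-binding proteins of transporters for spermidine and putrescine (LPU83_pLPU83c_0184) and for proline and glycine betaine (LPU83_pLPU83d_1299) rose by 2.22 ± 0.23 and 2.21 ± 0.30. The remaining members of the first 10 were the lytic murein transglycosylase gene LPU83_2746 at 2.23 ± 0.39, the OpgC gene LPU83_pLPU83c_0154 at 2.61 ± 0.48 and the valine tRNA gene LPU83_1650 at 2.63 ± 0.66. Single libraries moved the size of these last estimates: without pH 7.0 replicate 2 the first 2 stood at 2.92 and 3.57, and without pH 4.6 replicate 2, which held 138 CPM of the tRNA against 19.6 and 25.5 in its group, the tRNA gene stood at 1.19.

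Genes for proteins that handle heme or iron were among the 10 largest falls. The TonB-dependent heme receptor gene LPU83_2981 (chromosome 2929920 to 2932043), whose product takes up heme across the outer membrane, had a log2 fold change of -5.48 ± 0.28 (SE, edgeR adjusted p = 3.0e-06). The gene of the heme-degrading monooxygenase IsdG, LPU83_3140 (chromosome 3086205 to 3086519), fell by 3.996 ± 0.225 on the log2 scale, from 800 ± 72.2 CPM at pH 7.0 to 50.1 ± 10.8 CPM at pH 4.6 (SD, n = 3). The gene for an iron-binding protein of an ABC transporter, LPU83_2212, fell by 2.94 ± 0.27. TraA (LPU83_pLPU83b_0344) had the lowest estimate of the 10, -7.21 ± 0.60, and -8.05 without pH 4.6 replicate 2. Also in the first 10 were genes for a sorbitol and mannitol-binding protein (LPU83_3715, -3.75 ± 0.27), the Usg protein (LPU83_2220, -2.85 ± 0.37, and -2.24 without pH 7.0 replicate 1), an alkylhydroperoxidase of the AhpD family (LPU83_pLPU83d_1818, -2.69 ± 0.22), a sulfatase (LPU83_pLPU83c_0302, -2.61 ± 0.28) and a partitioning ATPase (LPU83_pLPU83d_0879, -2.54 ± 0.26). The last was the gene for an autoinducer synthesis protein, LPU83_pLPU83c_0631, of a family that makes the signal molecules of quorum sensing; it stood at -2.52 ± 0.43, and at -1.74 without pH 7.0 replicate 2. All 20 genes lay outside the range of the other group in each of the 3 libraries, a condition of the rule that named them. Of genes without a known product, 887 met the same conditions for a rise and 656 for a fall, with the largest rise in LPU83_2152 (4.87 ± 0.38) and the largest fall in LPU83_pLPU83b_0327 (-10.77 ± 0.61, and -10.05 without pH 7.0 replicate 2).

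**Figure D1:**
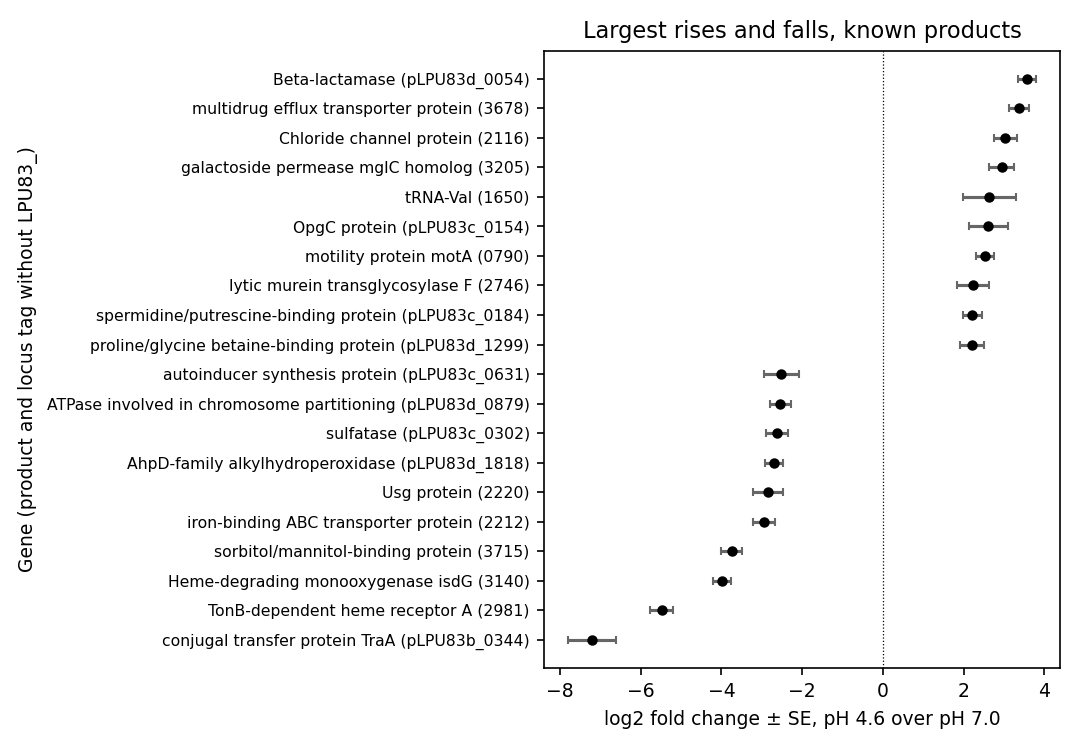
Log2 fold change at pH 4.6 over pH 7.0 on the horizontal axis for the 10 genes that rose most and the 10 that fell most among those with a known product, a mean log2 CPM of at least 5 and no overlap between the groups, one gene per line; points are edgeR estimates and bars are ± SE (n = 3 libraries at each pH). The estimates run from 3.58 for a beta-lactamase to -7.21 for TraA.

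These names reach only part of the genome. The deposited files give a product for 832 genes, 826 of which lie on the reverse strand, although the 7693 genes divide almost evenly into 3837 reverse and 3856 forward. Genes with a product text also had more counts, with a median log2 CPM of 6.19 against 4.51. Of the 826 such genes tested, 180 were higher and 223 lower. The strands themselves differed in balance: 684 of 3671 tested reverse genes were higher and 895 lower (median log2 fold change -0.08), against 845 and 749 of 3721 forward genes (median 0.04).

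Which known functions moved was asked of 29 gene lists fixed before the data were examined. At pH 4.6, 5 of 7 members of the list for the TCA cycle, the central pathway of respiratory carbon oxidation, rose and none fell, with a median log2 fold change of 1.07; 1 of the 5 is an enzyme of leucine synthesis. All 3 chemotaxis genes rose (median 1.49). Of the ribosomal protein genes 3 of 8 rose and none fell (median 0.76, and 0.56 without pH 4.6 replicate 2). Of the conjugation genes 3 of 4 fell (median -4.26, and -3.00 without pH 7.0 replicate 2). The camera test with a preset correlation of 0.01 called these 4 of the 18 lists with at least 3 tested genes, each with adjusted p = 0.023. With an estimated correlation none held, and each of the 4 had adjusted p = 0.43. The conjugation call was also lost with chromosomal scaling factors (adjusted p = 0.066).

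In the TCA cycle list, fumarase class I (LPU83_2238) rose by 1.43 ± 0.17 and aconitase (LPU83_3973) by 1.41 ± 0.17 on the log2 scale (SE). Succinate dehydrogenase cytochrome b-556 (LPU83_3926, 1.38 ± 0.24) and isocitrate dehydrogenase (LPU83_2283, 0.99 ± 0.23) rose too. The fifth that rose, 3-isopropylmalate dehydrogenase (LPU83_4105, 1.07 ± 0.17), is the enzyme of leucine synthesis, whose product text matched the list. Without it, an alternative chosen after the data were seen, 4 of 6 rose (median 1.19), with camera adjusted p = 0.049, or 0.44 with an estimated correlation. Fumarase class II (LPU83_2239) at -0.42 ± 0.25 and malate dehydrogenase (LPU83_3920) at 0.17 ± 0.20 did not pass. Adjusted over the list alone, 5 of the 7 members rose as well.

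Among the ribosomal protein genes 6 of 8 rose when adjusted over the list alone. Of those that passed only in this way, L33 (LPU83_1687) and L32 (LPU83_4086) leaned on pH 4.6 replicate 2. Without it they went from 0.76 and 0.77 to 0.43 and 0.37, while S2 (LPU83_2581) went from 0.56 to 0.68. The gene of L9 (LPU83_1392) rose by 1.47 ± 0.18 and that of S6 (LPU83_1395) by 1.27 ± 0.19. The chemotaxis members were motA (LPU83_0790, 2.53 ± 0.22), which the flagellum list also holds, and the chemoreceptor genes mcpA (LPU83_0671, 1.49 ± 0.27) and LPU83_3454 (1.16 ± 0.29); the same 3 passed over the list alone. In the flagellum list, the motor switch gene fliG (LPU83_0787) rose by 1.01 ± 0.24 and flagellin A (LPU83_2697) stood at 0.09 ± 0.19, so that 2 of 3 rose, over the list alone too (camera adjusted p = 0.061). In the conjugation list TraA, TrbF (LPU83_pLPU83a_0154, -3.84 ± 0.64) and TrbB (LPU83_pLPU83a_0161, -4.69 ± 0.75) fell, also over the list alone, and TraC (LPU83_pLPU83a_0140) stood at 0.41 ± 0.38. TrbF stood at -2.67 and TrbB at -3.34 without pH 7.0 replicate 2, where TrbB reached 126 CPM against 27.6 and 16.8 in the other pH 7.0 libraries.

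Of 16 genes for chaperones and stress proteases, 3 rose and 6 fell, with the same counts over the list alone and camera adjusted p = 0.56. The cold shock gene LPU83_0110 rose by 1.49 ± 0.38 (0.84 without pH 4.6 replicate 2, where it reached 178 CPM against 75.6 and 55.5) and the chaperonin gene Cpn10 (LPU83_0940) by 1.44 ± 0.42. The latter call was lost without pH 4.6 replicate 2, where the estimate was still 1.41, and with chromosomal scaling factors. Cpn10 varied mostly at pH 7.0, with 442, 1449 and 1906 CPM in replicates 1, 2 and 3. Its estimate was 1.04 without pH 7.0 replicate 1 and 1.86 without pH 7.0 replicate 3. A DnaJ-class chaperone gene (LPU83_pLPU83d_1507) fell by 1.80 ± 0.31 and hspQ (LPU83_2461) by 1.34 ± 0.26. Among 12 genes of oxidative stress and thiol redox, 3 rose and 3 fell, over the list alone too, with camera adjusted p = 0.93 and a median of -0.02 against a mean of 0.01. Hydroxyacylglutathione hydrolase (LPU83_2367), lactoylglutathione lyase (LPU83_0450), which together form the glyoxalase pathway that detoxifies methylglyoxal, and a glutathione S-transferase (LPU83_pLPU83d_1146) rose by 1.42 ± 0.17, 1.40 ± 0.21 and 1.93 ± 0.27. The AhpD-family gene, glutaredoxin 4 (LPU83_2298, -0.88 ± 0.22) and catalase/peroxidase (LPU83_3327, -0.61 ± 0.17) fell.

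In the list of cell division and peptidoglycan 3 of 5 rose, over the list alone too (camera adjusted p = 0.22), among them the peptidoglycan O-acetyltransferase gene yrhL (LPU83_3344, 1.01 ± 0.20) and the MurC-type ligase gene (LPU83_2733, 0.71 ± 0.17). Of 4 membrane lipid and lipopolysaccharide genes, phosphatidylserine decarboxylase (LPU83_1366) rose by 0.53 ± 0.17 and the lipid A exporter gene msbA (LPU83_2943) fell by 0.67 ± 0.17. Over the list alone 1 rose and 2 fell (camera adjusted p = 0.90). The decarboxylase call was lost under 5 alternatives, chromosomal scaling factors among them. The exopolysaccharide gene LPU83_1172 fell by 0.94 ± 0.29, a call lost when any one of pH 4.6 replicates 1 and 3 or pH 7.0 replicate 1 was left out, and polyhydroxyalkanoate synthase (LPU83_1931), which makes storage polymer, fell by 0.93 ± 0.21.

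Of 23 ABC transporter genes 3 rose and 7 fell, or 4 and 9 over the list alone (camera adjusted p = 0.19); a sugar-binding protein gene (yurO, LPU83_2786) rose by 1.04 ± 0.22. The proline and glycine betaine gene given above also rose, and the sorbitol and iron-binding genes given above fell. The list of compatible solutes held 3 genes, of which that proline and glycine betaine gene rose, over the list alone too (camera adjusted p = 0.66, median -0.17 and mean 0.50). In the iron list the heme receptor fell, and an iron(III)-binding protein gene (LPU83_4040) at 0.49 ± 0.19 passed over the list alone but not over all genes. Of 10 transposase and integrase genes 4 fell, over the list alone too (camera adjusted p = 0.19), among them LPU83_pLPU83a_0039 (-1.48 ± 0.26) and LPU83_pLPU83c_0687 (-1.37 ± 0.29); reads of such repeated genes can be assigned to more than one copy.

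In the largest list, 57 transcriptional regulators, 3 rose and 12 fell, or 2 and 12 over the list alone (camera adjusted p = 0.31). A LacI family gene (LPU83_3745) fell by 1.76 ± 0.28 and an HTH-type regulator gene (LPU83_pLPU83c_0629) by 1.39 ± 0.19, while a GntR family gene (LPU83_0414) rose by 0.76 ± 0.17. A sugar metabolism regulator gene (LPU83_pLPU83d_1550) rose by 0.71 ± 0.22, a call lost under 6 alternatives. In nitrogen assimilation 1 of 5 members fell, over the list alone too, namely the nitrogen regulator NR(I) (LPU83_3533, -0.95 ± 0.25; camera adjusted p = 0.81). Among 4 aminoacyl-tRNA synthetase genes that of tyrosine (LPU83_2331) rose by 0.70 ± 0.19, over the list alone too (camera adjusted p = 0.66), a call lost without pH 4.6 replicate 3 or pH 7.0 replicate 2.

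No member passed, over all genes or over the list alone, among the 4 members of the sigma factor list, 1 of them an anti-sigma factor (camera adjusted p = 0.94), 4 genes of urease and its accessory proteins (0.81) or 3 of the pentose phosphate and Entner-Doudoroff pathways (0.90). Single members stood for the respiratory complexes. The delta subunit gene of ATP synthase (LPU83_3903) rose by 0.79 ± 0.20, a call lost with chromosomal scaling factors. The iron-sulfur subunit gene of the cytochrome bc1 complex (LPU83_2939) rose by 1.13 ± 0.16. A subunit gene of NADH dehydrogenase (LPU83_pLPU83d_0712) stood at -0.72 ± 0.28 (edgeR adjusted p = 0.059), and pyruvate carboxylase (LPU83_4099), the one member for gluconeogenesis, at 0.14 ± 0.18. The list with urease also asked for amine-producing decarboxylases, which no product text matched, so these were not examined. No gene with a product text matched the lists of known acid-response genes, potassium uptake, phosphate acquisition or nodulation and nitrogen fixation, so nothing is said of them here.

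**Figure D2:**
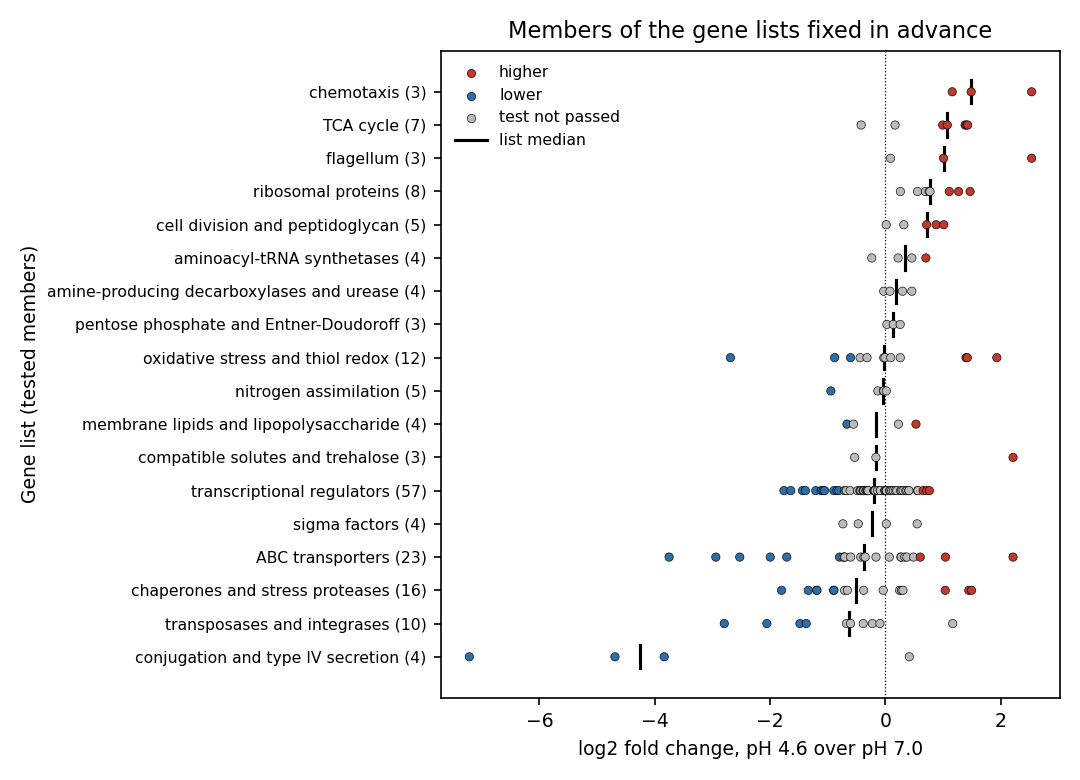
Log2 fold change at pH 4.6 over pH 7.0 on the horizontal axis of each tested member, for the 18 gene lists with at least 3 tested genes; red points are genes higher and blue points genes lower by edgeR, grey points did not pass, and bars are list medians. Medians run from 1.49 for chemotaxis to -4.26 for conjugation (-3.00 without pH 7.0 replicate 2), and the chromosomal scaling factors would move each point by about -0.23.

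How the change was spread over the chromosome and plasmids was asked next. Plasmid pLPU83b stood apart, since most of its transcripts fell. It took 21.9 ± 7.06% of all counts at pH 7.0 and 3.68 ± 0.36% at pH 4.6 (SD, n = 3). Of its 547 tested genes 416 fell (76.1%) and 5 rose. The chromosome took 65.4 ± 6.10% of counts at pH 7.0 and 86.3 ± 1.02% at pH 4.6.

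Shares of the other plasmids differed less. That of pLPU83a was 1.02 ± 0.058% at pH 7.0 and 0.798 ± 0.033% at pH 4.6, that of pLPU83c 2.99 ± 0.23% and 2.27 ± 0.21%, and that of pLPU83d 8.66 ± 0.80% and 6.93 ± 0.45%. At pH 7.0 the share of pLPU83b was 30.1% in replicate 2 against 18.4% and 17.3% in the others. With 3 libraries against 3, an exact two-sided permutation test cannot go below p = 0.10, so no test of these shares is given. For the chromosome and for each plasmid the shares of the 2 groups did not overlap. The shares of a library form a whole, so these differences are not independent. The smaller share of pLPU83b at pH 4.6 raises all other shares there, that of the chromosome included. Relative to the chromosome, whose share rose, the other plasmids fell by more than their shares show.

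**Figure D3:**
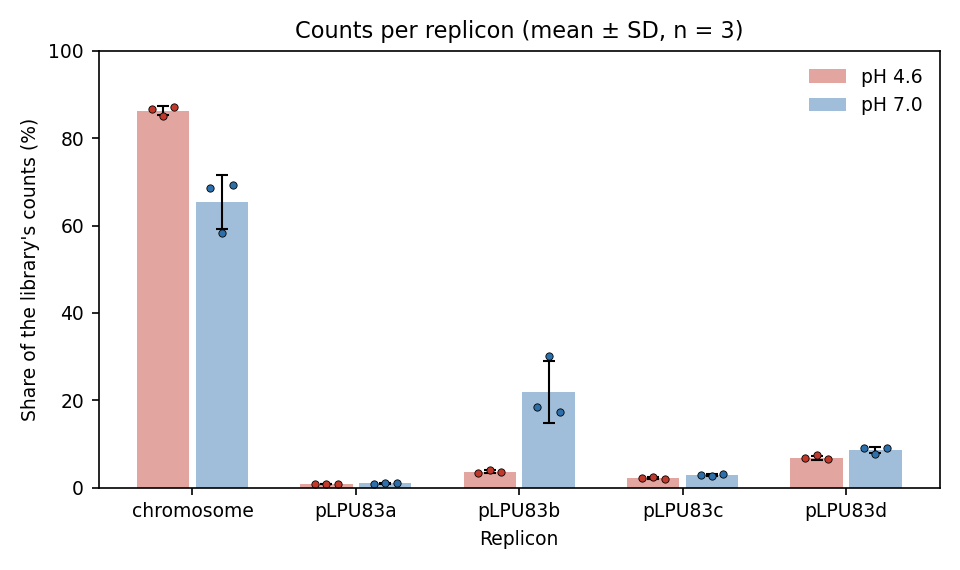
Share of each library's counts (%, vertical axis) on the chromosome and on each plasmid; bars are means, error bars are ± SD and points are the 3 libraries at pH 4.6 (red) and at pH 7.0 (blue). On pLPU83b the mean was 3.68% at pH 4.6 and 21.9% at pH 7.0, with one pH 7.0 library at 30.1%.

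The median log2 fold change of pLPU83b genes was -1.45, with quartiles at -2.07 and -0.97, and 377 genes were at least 2-fold lower. On the chromosome the median was 0.22, or -0.01 with chromosomal scaling factors, under which pLPU83b stood at -1.68. Of 4100 chromosomal genes 1204 rose (29.4%) and 576 fell (14.0%); with chromosomal scaling factors 850 rose. On pLPU83d 210 of 1850 genes rose and 438 fell, on pLPU83c 98 of 743 rose and 173 fell, and on pLPU83a 12 of 152 rose and 41 fell. By Fisher's exact test, two-sided and adjusted over 10 tests, falling genes were more frequent on pLPU83b than elsewhere (odds ratio 14.5, adjusted p = 7.0e-173) and rising genes were less frequent there (adjusted p = 1.3e-48). Rising genes were more frequent and falling genes less frequent on the chromosome (adjusted p = 7.2e-99 and 3.7e-79). Rising genes were less frequent on pLPU83a, pLPU83c and pLPU83d (adjusted p = 3.7e-05, 5.8e-08 and 7.7e-33), while their falling genes did not pass (0.19, 0.49 and 0.11). Each test set a replicon against all others, pLPU83b included. The shares of falling genes on pLPU83a, pLPU83c and pLPU83d were 27.0%, 23.3% and 23.7%, above the 14.0% of the chromosome, a contrast not tested alone. Genes of one operon move together and are not independent, so these p-values describe where the calls lie.

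**Figure D4:**
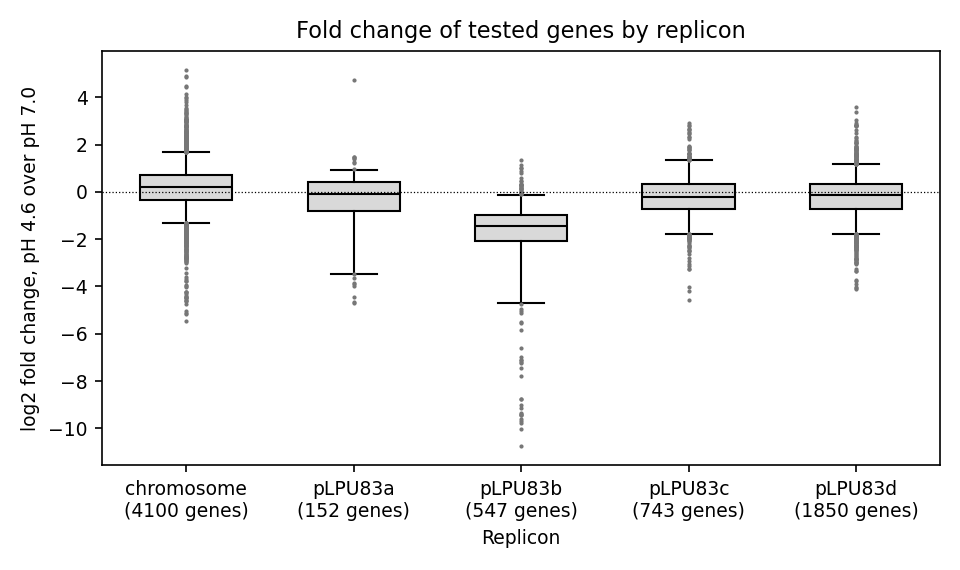
Log2 fold change at pH 4.6 over pH 7.0 (vertical axis) of all tested genes on the chromosome and the 4 plasmids; boxes span the quartiles, lines are medians, whiskers reach the 5th and 95th percentiles and points are genes beyond them. The median of pLPU83b is -1.45 and that of the chromosome 0.22, and chromosomal scaling factors put them at -1.68 and -0.01.

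Of the 58 sequences of pLPU83b, contig 34 was singled out after its values were seen. It held 21 of the 32 genes that lay more than 3 log2 units below the plasmid's median, and the other 11 lay on other sequences, among them LPU83_pLPU83b_0366 on contig 36 at -9.03. On contig 34, 21 of 40 tested genes lay below a log2 fold change of -5, between positions 18550 and 41431. They include the operon from LPU83_pLPU83b_0325 to LPU83_pLPU83b_0329, 5 genes without a product text that all fell (median -9.78; -10.68 without pH 4.6 replicate 2 and -9.04 without pH 7.0 replicate 2), and the operon from LPU83_pLPU83b_0341 to TraA, 4 genes that all fell (median -7.17, and -7.97 without pH 4.6 replicate 2). The neighbouring replication genes RepB (LPU83_pLPU83b_0323) and RepA (LPU83_pLPU83b_0324) stood at -1.72 and -1.64. Median CPM of the 21 genes at pH 7.0 was 8255 in replicate 2 against 3172 and 2515 in replicates 1 and 3.

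**Figure D5:**
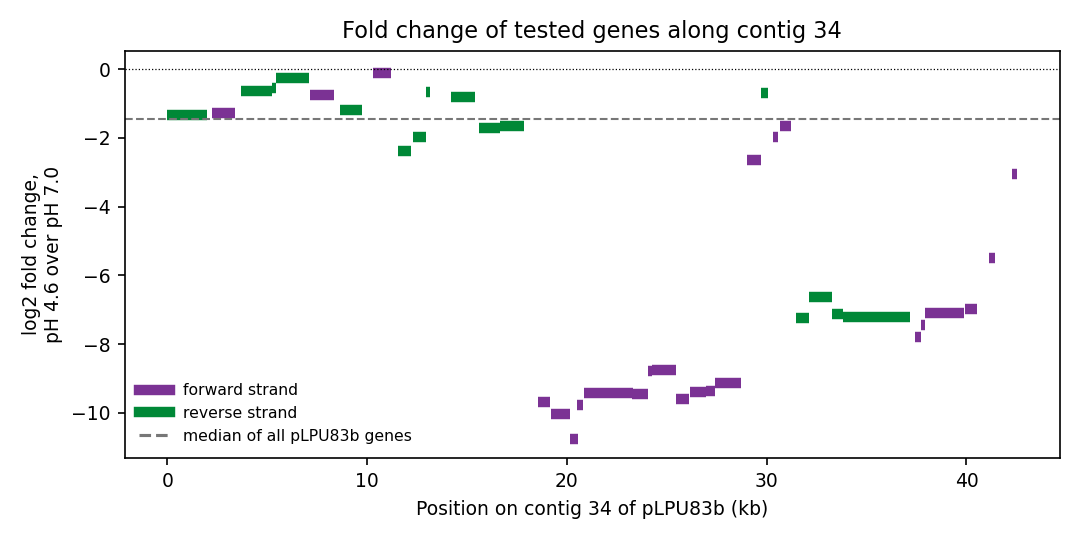
Log2 fold change at pH 4.6 over pH 7.0 (vertical axis) along contig 34 of pLPU83b (kb, horizontal axis); each bar spans a tested gene, coloured by strand, and the dashed line is the median of all pLPU83b genes, -1.45. The 21 genes below -5 lie in separate groups between 18550 and 41431 bp.

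The authors' own comparison of the same libraries, deposited as a DESeq2 table, was set beside these calls. It held 3313 genes with an adjusted p under 0.05, 1604 higher and 1709 lower at pH 4.6, of which 1899 were at least 2-fold apart. Of the edgeR calls 3135 were among them with the same sign, none had the opposite sign and 38 were missing, while 161 of the authors' calls among tested genes were not made by edgeR. Across genes, which are not independent replicates, the 2 sets of log2 fold changes correlated with Pearson's r = 0.996. Both rest on the same counts, so this compares the computation alone.

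Whether genes transcribed as one unit changed together was asked with the authors' list of 1372 operons, which hold 3880 genes. Genes of one operon mostly moved the same way. The operon with fliG and motA (LPU83_0787 to LPU83_0790) had all 4 genes higher (median log2 fold change 1.79), and the one that begins with the mglC homolog (LPU83_3205 to LPU83_3201, on the reverse strand) all 5 (median 3.02). That of ATP synthase delta (LPU83_3898 to LPU83_3903) had all 6 higher (median 0.79). On pLPU83a the operon with TrbF and TrbB (LPU83_pLPU83a_0151 to LPU83_pLPU83a_0161) had all 11 genes lower, with a median of -3.84, and -2.66 without pH 7.0 replicate 2.

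All tested members were higher in 162 operons and all lower in 195; members passed in opposite directions in 16, and no member passed in 532. Over 2446 neighbouring pairs in one operon, Pearson's r of the log2 fold changes was 0.91, against 0.56 over 2409 neighbouring pairs on the same strand that were not in one operon. The difference of 0.345 had p = 1e-05 in a two-sided permutation test, the smallest that its 100000 resamples can give; genes are not independent replicates, and this was the single relation tested in its family. Where both genes of a pair passed, 808 of 812 operon pairs (99.5%) and 496 of 581 other pairs (85.4%) moved the same way. The median distance between the genes was 5 bp in operon pairs and 141 bp in the others, and 910 of the operon pairs overlapped against 144 of the others, so the classes also differ in spacing. Without overlapping pairs, an alternative chosen after the data were seen, r was 0.90 over 1536 pairs and 0.54 over 2265, a difference of 0.363 (permutation p = 1e-05). The operons were called on reads of these same libraries.

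The authors' list of transcription start sites was described last. It held 4205 sites, 2044 on the forward and 2161 on the reverse strand, found in the pooled reads of the 6 libraries, so that no site belongs to one pH. A gene lay downstream of 1595 sites, at a median distance of 53 bp (quartiles 19 and 120). The longest distance was 300 bp, equal to a limit that the authors' search set for leaderless transcripts, so genes farther away may be left out. In all, 1375 genes had a site upstream. Of these genes 1368 were tested, of which 339 were higher and 309 lower at pH 4.6. The list marked 89 sites as leaderless, meaning a transcript with hardly any untranslated leader, 3697 as primary and 508 as secondary. It placed 2230 in a class for transcripts outside the annotated genes, 1266 on the forward and 964 on the reverse strand. By contrast, 631 forward and 964 reverse sites had a gene downstream. Genes divide almost evenly between the strands, so the assignment of sites to genes may differ by strand, which was not tested. Of the sites on pLPU83b 365 of 401 were in that class, against 62 of 83 on pLPU83a, 257 of 353 on pLPU83c, 658 of 893 on pLPU83d and 888 of 2475 on the chromosome. The median site had 81 read starts, summed over the 6 libraries.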

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

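TMM factors from chromosomal genes and the TCA cycle list without a leucine enzyme were chosen after seeing the data. So were the leave-one-out, block and no-overlap values of the operon comparison, and the medians of operons and lists without each library. The other alternatives were fixed beforehand. Of 154 alternative values for the 11 main results, 148 kept their direction and stayed within 1.5 times the count. With chromosomal TMM, 535 genes were at least 2-fold higher against 826; the factors shift all genes by -0.23, and 2692 of the 3173 calls were shared. Testing against a 2-fold change with glmTreat gave 789 genes in place of 1965, 294 higher and 495 lower, since it asks that the change exceed 2-fold beyond its error. With an estimated correlation camera called 0 lists, where the 4 had unadjusted p between 0.112 and 0.161, 0 lists had one under 0.05 and the lowest was 0.073 for the flagellum; fry called 9, since it does not compare a list with other genes.

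Without each library in turn, the number of changed genes lay between 2453 and 3534, highest without pH 4.6 replicate 2. Genes higher numbered 1166 to 1776, lower 1258 to 1758, changed at least 2-fold 1808 to 2076, 2-fold higher 781 to 837 and 2-fold lower 1027 to 1239. On pLPU83b 344 to 442 genes were lower, and 915 to 1435 chromosomal genes were higher. From 4 to 5 lists and 6 to 8 replicon tests passed, and the operon difference lay between 0.326 and 0.359. The cause of these ranges was not tested beyond the smaller number of samples.

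With the replicate number as a block, edgeR called 3234 genes. Deviations of libraries with the same number from their group correlated across genes at 0.05, 0.21 and 0.07. For libraries with different numbers these correlations lay between -0.18 and 0.12. The value for number 2 was the highest of all, so whether the numbers pair the samples cannot be told from these values.

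Of 741 alternative values for the 53 named genes, 722 kept the call, 19 lost it and 0 changed sign; of 271 for the 18 tested lists, 259 kept their side of the threshold. DESeq2 shared 3151 calls. Depth limits little here; low-count genes among the 301 not tested are the exception.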

Other observations

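All tests in this part were chosen after the results they bear on had been seen, except the test of the hexamer on the plasmids, which was set before its result was known.

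Long stretches of neighbouring genes moved together at pH 4.6, many without a product text. There were 51 runs of at least 6 neighbouring genes that were all called and all at least 2-fold changed in one direction, 14 higher and 37 lower, with 445 genes in all. Neighbouring genes, above all those of one operon, already moved together, so no test of this number is given. On the chromosome, 17 genes from LPU83_0787 to LPU83_0803, with fliG and motA among them, were higher (median log2 fold change 2.07), and so were 12 genes from LPU83_0771 to LPU83_0782 (1.66) and 6 from LPU83_0811 to LPU83_0816 (1.94). Further runs of higher genes reached from LPU83_1655 to LPU83_1671 (17 genes, 2.23), from LPU83_1741 to LPU83_1746 (6 genes, 3.73) and on pLPU83d from LPU83_pLPU83d_0287 to LPU83_pLPU83d_0293 (7 genes, 2.50).

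Of the 37 lower runs 17 lay on pLPU83b, 9 on pLPU83d, 7 on the chromosome, 3 on pLPU83c and 1 on pLPU83a. On the chromosome, the run from LPU83_3140, the isdG gene, to LPU83_3151 spanned 12 genes (median -2.83), that from LPU83_2205 to LPU83_2213, which holds the iron-binding LPU83_2212, spanned 9 (-2.40), and that from LPU83_3710 to the sorbitol and mannitol-binding LPU83_3715 spanned 6 (-4.89). A run of 10 genes from LPU83_3738 to LPU83_3747 (-2.14) holds the LacI family regulator LPU83_3745, a sugar transporter gene and an efflux gene. On pLPU83d, a pair of runs with efflux and membrane protein genes, from LPU83_pLPU83d_0786 to LPU83_pLPU83d_0792 (7 genes, -2.98) and from LPU83_pLPU83d_0794 to LPU83_pLPU83d_0803 (10 genes, -2.48), stood side by side. These runs were not tested one by one.

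The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. By edgeR the real division gave 3173 changed genes, 1965 changed at least 2-fold and 416 lower on pLPU83b, against at most 0 in each other division, so that it was the 1 of 10 for each of these. Each other division mixes the pHs on both sides, so the pH difference widens the spread within sides. Their 0 calls therefore do not measure how often false calls arise. For gene lists the real division gave 4 calls, and another division also gave 4, so that 2 of 10 reached that number.

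Most genes of pLPU83b were lower at pH 4.6. The median of its genes lay -1.67 log2 units from that of the chromosome. A scaling factor moves both alike, so scaling cannot account for this fall. It was not limited to the 20 most abundant genes, as 75.3% of the other 527 genes were lower. With 416 of 547 genes lower, leaving out 20 could hardly move that share. The count therefore does not test what part abundant genes play. A loss of plasmid copies would lower all its genes by a like amount. That does not account for the 32 genes (5.85%) more than 3 log2 units below the plasmid median. On the chromosome 0.878% of genes lay as far below the chromosome's own median. Of the 32 plasmid genes 21 lie on contig 34. For the remaining genes a common shift stays open. Their interquartile range was 0.934 times that of the chromosome, from which no genes were removed, so the removal itself narrows the former. The remaining genes held 3.63 ± 0.33% of counts at pH 4.6 and 9.69 ± 1.04% at pH 7.0. No DNA was measured here, so fewer plasmid copies, cells without the plasmid, loss of part of it and regulation by pH may each play a part and cannot be told apart for these genes.

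At pH 4.6, replicate 2 lay apart from replicates 1 and 3. Its deviation fell with gene length (Spearman's rho across 3446 genes -0.26), with a median of 0.53 log2 units for 196 genes under 150 bp and 0.015 for the others. The length trend is not the whole of it: the SD of the deviation went from 0.561 to 0.537 when the trend was removed, still 2.72 times that between replicates 1 and 3. The label of this library gives a single index sequence and those of the other 5 give 2, so 1 library may come from another preparation. A different culture cannot be told apart from that, and no biological explanation was tested.

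The bases at the listed start sites do not resemble those of usual bacterial promoters, which start mostly on a purine behind an A and T rich element. Only 40.6% of sites began with a purine, against 48.4% in flanking sequence, and the richest 6-base window within 20 bases upstream exceeded the flank of 45.4% A and T by 2.61 points. C stood at 51.5% of sites, and its share was 4.18 points higher at sites with a gene downstream than at the others. This is consistent with a base preference where reads begin, for instance at fragment ends, for part or most of the list. Which sites are true starts was not tested, and no biological explanation was tested.

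One hypothesis concerns conjugation. TraA and its neighbours on pLPU83b, the operon with TrbB (LPU83_pLPU83a_0161) on pLPU83a and the autoinducer synthesis gene LPU83_pLPU83c_0631 all fell at pH 4.6 and may answer to one signal, such as quorum sensing, which controls plasmid transfer in several rhizobia. If so they should also vary together among libraries of one pH. At pH 7.0 replicate 2 had more of all of them. The median CPM of the TraA operon was 2720 against 1363 and 1743, that of the 11 genes of the pLPU83a operon 77.7 against 16.2 and 16.4, and that of the autoinducer gene 127 against 40.6 and 39.9. Relative to replicates 1 and 3, the last 2 lay at or above the 99.2 percentile of all genes and the TraA operon at the 94.4 percentile. The pH 4.6 libraries go against it: there the TraA operon stood at 30.5 CPM in replicate 2 against 8.07 and 8.19 (99.5 percentile), while the pLPU83a operon (3.08 against 2.67 and 3.02) and the autoinducer gene (11.6 against 11.8 and 12.8) did not follow, at the 50.1 and 42.9 percentiles. Nor did the other gene with such a product, LPU83_pLPU83a_0051, which rose by 1.45 ± 0.18 at pH 4.6 and lay at the 44.3 percentile in pH 7.0 replicate 2. The contrast at pH 4.6 is limited too, since the pLPU83a operon had few counts there and replicate 2 lay apart from its group. The hypothesis stays open, as each comparison rests on 1 library and the pH 7.0 values had been seen in part before the test. In addition, pH 7.0 replicate 2 enlarged the falls by which these genes were picked. Without it the median of the pLPU83a operon went from -3.84 to -2.66, and the autoinducer gene fell less too. High values in that library are therefore partly a matter of how the genes were picked. Cell density, on which such signals depend, is not in the labels either.

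Another hypothesis concerns the chromosome genes that rose. The hexamer TTAACC, the first part of the textbook binding site of the cell-cycle and motility regulator CtrA, stood upstream of 18 of 315 higher genes with a start site and 7 of 786 others. Corrected over 3580 hexamers in 2 scans, Fisher's one-sided p was 0.049, so a shared upstream element may be involved. An earlier count by site instead of by gene had given a smaller p. Sequences of all sites of a gene were scanned together, so genes with more sites offered more sequence, for which no adjustment was made. The test also takes genes as independent, although the neighbours LPU83_0809 and LPU83_0810 are both among the 18. The sequences scanned lie upstream of the listed sites, part or most of which may reflect the base preference described above. Among the 18 is LPU83_0771, the first gene of an operon of 10 higher genes near the motility genes. Only 1 plasmid gene carried the hexamer, so the same test could not be run there. In lower genes the best hexamer did not pass (Fisher's exact test, one-sided, corrected p = 0.15).

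Fold changes also varied along the chromosome as a shallow wave, as a change in gene dosage from origin to terminus might give. Its amplitude was 0.16 log2 units with a peak at 1072470 bp (block permutation p = 0.026 with blocks of 50 genes and 0.0086 with blocks of 200), but the position of the origin is not known here and the wave was found among several patterns looked at.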
